A study of Mus musculus with 6 samples.

How the data were processed

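Gene expression was measured on 6 one-colour microarrays hybridised with biotin-labelled total RNA from the subventricular zone (SVZ), the neurogenic wall of the lateral ventricle, of adult male C57BL/6 mice. Per the labels, 3 arrays came from mice killed 48 h after middle cerebral artery occlusion (MCAO), a stroke model in which the artery feeding the striatum and lateral cortex is blocked, with the SVZ taken on the lesioned side. The other 3 arrays came from mice killed 48 h after sham surgery. Per the labels' protocols the SVZ was dissected within minutes, stored in RNAlater and extracted with an Ambion total RNA kit.

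The deposited values are log2 expression values, 1 per probe set, on a scale from about 5 to 15 for 45101 probe sets with Affymetrix-type names, of which 64 are manufacturer's controls. The background correction, the summary of probes and the normalization used by the authors are not given in the sources used here, so a generalised logarithm, which would compress low values, cannot be excluded. The medians of the deposited log2 values lay between 6.57 and 6.59 on all 6 arrays. Their 90th percentiles ran from 8.85 to 9.06, so quantile normalization between arrays was added, as the design fixed before the data were examined required where quantiles differed; the values as deposited were analysed as an alternative. On the deposited scale the median gene differed by 0.0071 log2 between MCAO and sham.

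Probe sets were named from the array's annotation table, which gave 1 gene symbol to 34958 of them, several to 932 and none to 9211. Of the 34958, 34754 were found by gene number in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. Only probe sets with 1 symbol were used for genes. Where a gene had several (9012 genes), the one with the highest mean over all 6 arrays stood for it, which left 18194 genes. Probe sets whose names end in _s_at or _x_at may bind transcripts of related genes; 13 of the 126 genes named in the text rest on such a probe set.

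MCAO was compared with sham by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), 2-sided, with Benjamini-Hochberg adjustment over the 18194 genes and a threshold of 0.05 on the adjusted p. Differences are MCAO minus sham on the log2 scale with limma's moderated standard error (SE), and means carry the standard deviation (SD) of 3 arrays. The number of arrays limits the precision. Nothing in the labels says that each array held tissue of a separate mouse, so the p-values measure only the spread between these samples, which may be technical. A rank-based or permutation test of 3 samples against 3 cannot go below p = 0.1, 2-sided.

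Gene lists were fixed before the data were examined: 36 lists, 18 of pathways and 18 of cell type markers, with 843 entries for 798 distinct genes. Of the entries, 770 were measured, 3 of them under an older symbol, and 73 were not matched to a probe set with 1 symbol. The lists cover the Notch pathway, the hypoxia response, astrocytic calcium wave machinery, S100 and annexin genes, 3 sets of reactive astrocyte genes, cytokines and chemokines, growth factors acting on neural progenitors, the type I interferon response, complement, antigen presentation, the cell cycle, immediate early genes, heat shock and unfolded protein genes, extracellular matrix, cholesterol synthesis and synaptic transmission. The marker lists cover neural stem cells, transit-amplifying progenitors, neuroblasts, astrocytes, homeostatic microglia, activated phagocytes, infiltrating monocytes or macrophages, neutrophils, lymphocytes, ependymal cells, choroid plexus, mature oligodendrocytes, oligodendrocyte precursors, striatal neurons, cortical, hippocampal or septal neurons, endothelial cells, mural cells or fibroblasts, and red blood cells. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists, and again with a correlation estimated from the data. The number of members past the threshold was counted after adjustment over all genes and adjusted over the list alone.

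The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 MCAO values lay on one side of all 3 sham values, leaving out predicted genes. Where fewer than 10 passed in a direction, the smallest p-values in that direction followed. It adds the 3 members of each list with the smallest p, and always Gfap, Vim, Nes, Notch1, Jag1, Hes1, Hes5, Gja1, Vegfa, Dcx and Mki67. Of the 126 genes so named, 67 had several probe sets, and 1, Dclk1, had another probe set with an opposite difference at an unadjusted p under 0.05.

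The labels number the samples 1 to 3 in both groups without saying what the numbers mean. Deviations from the group means correlated across genes at 0.77 between the arrays numbered 1, 0.44 between those numbered 2 and 0.48 between those numbered 3, each the highest value of its array with the other group. By the criterion that every same-numbered pair exceed 0.1, the numbers were taken to pair the samples, a pairing that comes from the data and not from the labels. The differently numbered MCAO 3 and sham 2 also exceeded it, at 0.29, so the criterion alone does not set pairs apart. Deviations from a group mean cancel out within the group, so the 0.77 by itself raises the values among the arrays numbered 2 and 3. Their 0.44 and 0.48 are thus no independent evidence of pairs, though they exceed the 0.29 and the 0.027 of MCAO 2 with sham 3. Since the pairing was taken from the data it is then used on, p-values with the block may be too small. The main comparison has no block, as fixed beforehand. The comparison with the sample number as a block is given beside a result where it changed the call or moved a count by over 1.5 times.

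The procedure was tested on 10 simulated data sets of 18194 genes with 200 changed genes for this comparison, using the spread of the real arrays. With no pair effect, limma without the block recovered 58.0% of genes changed 1.5-fold and 91.2% of those changed 2-fold. With the pair effects seen in the data it recovered 42.0% and 92.2%, and with the block 97.8% and 100%. A list raised in the simulations, that of the cell cycle, was called in all of them at the preset correlation. Apart from the pair effects, the noise of each gene was drawn independently, while the correlation estimated from the data for this list was 0.345. The simulations therefore do not show how camera at the preset correlation behaves with genes so correlated. With an estimated correlation and the pair effects seen it was called in a share of 0.9 without the block and 0.3 with it. Alternatives tried were the deposited values without quantile normalization or shifted to a common median, a filter on dim genes, the mean of all probe sets of a gene, each probe set on its own, other variance models, array weights, the block, leaving out each array in turn, other thresholds, camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The gene table served for names only, and no genome positions are given.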

Results

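The subventricular zone was profiled 48 h after stroke surgery, with 3 MCAO and 3 sham arrays and 18194 genes measured on each. By its title the study concerns how injury reaches the neural stem and progenitor cells of this niche, with calcium waves in astrocytes as the signal. The arrays correlated across genes at Pearson's r between 0.975 and 0.992 with quantile-normalised values, and no pair of arrays held identical values for any gene. The arrays numbered 1 stood apart from the other 4 in both groups along the principal component that held 40.8% of the variance, while a second component with 33.8% separated MCAO from sham. The poly-A control probe sets, which report RNA spiked in at labelling, averaged 7.69 log2 on MCAO 1 and 7.96 on sham 1 over 24 probe sets, against 8.65 to 9.23 on the other 4 arrays. The 5′ control probe set for 18S ribosomal RNA read 11.3 on MCAO 3 and between 7.41 and 9.16 on the other arrays.

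**Figure D1:**
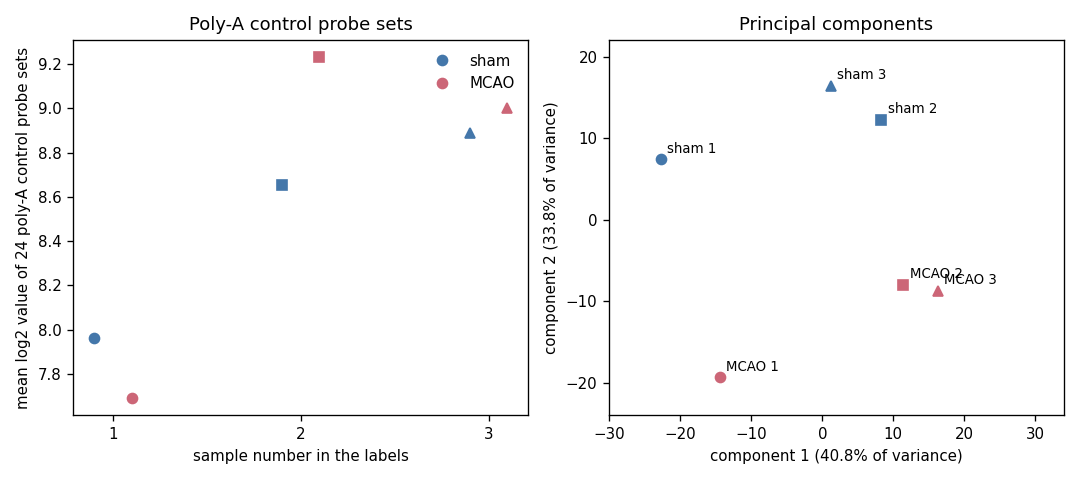
Left, mean deposited log2 value of the 24 poly-A control probe sets on each array, by sample number and group; right, each array's position on the principal components of all 18194 genes, with 40.8% and 33.8% of the variance. The arrays numbered 1, at 7.69 for MCAO and 7.96 for sham, lie below the other 4 on the left and apart from them along the horizontal axis on the right.

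MCAO tissue differed from sham mainly by genes that rose. Serpina3n, a protease inhibitor secreted by reactive astrocytes, rose most, by 3.05 ± 0.24 log2 (SE, n = 3 per group), or 8.27-fold. Lgals1 and Lgals3, which encode galectins, rose 7.89-fold and 4.90-fold, and Vim, an intermediate filament of astrocytes and other glia, rose 5.08-fold. The other 6 largest rises were those of Ccl12, a monocyte-attracting chemokine, at 2.30 log2, the lysosomal protease gene Ctsc at 2.25, the cytokine-signalling inhibitor Socs3 at 2.02, the sphingosine-1-phosphate receptor S1pr3 at 2.01, the hyaluronan receptor Cd44 at 1.97 and the lysozyme gene Lyz1 at 1.96. Socs3 and Lyz1 were read by probe sets that may also bind related transcripts. By limma's moderated test with Benjamini-Hochberg adjustment, 206 genes passed the threshold, of which 203 rose and 3 fell. On the values as deposited, with arrays shifted to a common median and with the mean of a gene's probe sets, all 206 had the same direction, and 169, 168 and 165 of them passed. In all 206 the 3 MCAO values lay on one side of the 3 sham values, which passing this test all but requires; over all genes measured the share was 13.8%, against 10% by chance. At least 2-fold changes numbered 70, all of them rises, with 1 fall among 91 with the sample number as a block, 5 among 76 without MCAO 1 and 6 among 81 without both arrays numbered 1. Among the 10 largest, Ccl12 (adjusted p = 0.0900 and 0.0685) and Lyz1 (0.108 and 0.0998) lost their calls without sham 3 or MCAO 3, Socs3 without sham 3 or MCAO 2 (0.113 and 0.0600), and Lgals3 without sham 3 (0.0743).

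The 3 genes that fell were Gas7, a growth-arrest-specific gene expressed in neurons, which fell by 0.86 ± 0.14 log2 (SE, n = 3 per group; adjusted p = 0.0366), the immediate early transcription factor Egr1, which fell by 0.47 (adjusted p = 0.0498), and Entpd3, an ectonucleotidase that hydrolyses extracellular ATP, which fell by 0.43 (adjusted p = 0.0496). By limma on the values as deposited 188 genes rose and 0 fell, and with arrays shifted to a common median 184 rose and 0 fell, with 1377 and 1337 genes at an unadjusted p under 0.05. There Gas7 read −0.83 and −0.85 (adjusted p = 0.0678 and 0.0646), Egr1 −0.43 and −0.44 (0.231 and 0.229), and Entpd3 −0.40 and −0.41 (0.124 and 0.120). The differences thus stayed close in size while the adjusted p no longer passed, and with the block on the values as deposited all 3 passed (3.08e-04, 0.0349 and 0.0260). Egr1 and Entpd3 did not pass with robust variance (0.0509 for both) or with dimmer genes left out (0.0806 and 0.0896), nor Egr1 with an intensity trend (0.0892), and with the mean of its probe sets Gas7 read −0.25 (0.198). Falls numbered 21 without MCAO 1 and 26 without both arrays numbered 1. The next 7 genes by p among those lower in MCAO did not pass. They were Kalrn, a regulator of dendritic spines (−0.42, adjusted p = 0.0711), the dynein subunit Dync1i1 (−0.35, 0.0731), the synaptic protein gene Lgi1 (−0.40, 0.080), Egr2 (−0.76, 0.0815), the Notch target Hes5 (−0.42, 0.0815), the synaptic adhesion gene Lrfn5 (−0.33, 0.0828) and Vat1l (−0.59, 0.0875). Without MCAO 1, Egr2 and Vat1l passed (0.0199 and 0.0320). With the sample number as a block all 7 passed, at adjusted p between 0.00361 for Egr2 and 0.0176 for Lrfn5. The block raised the number of genes past the threshold to 1113, of which 877 rose and 236 fell, with all 206 among them; on the deposited scale the same block gave 816 genes, 765 rising and 51 falling. The count of 206 depended on single arrays: it was 44 without sham 3, 98 without MCAO 3, 125 without sham 1 and 132 without sham 2. That of 2-fold changes was 31 without sham 3. All 206 genes kept their direction whichever array was left out. Without sham 3, Ccl12, Lgals3, Socs3 and Lyz1 read 2.20, 2.24, 1.93 and 1.94, against 2.30, 2.29, 2.02 and 1.96 with all arrays. These fits have 3 arrays against 2, so a lost call alone does not show that a difference rests on the array left out. Of the 49 named genes past the threshold, 19 kept that call whichever array was left out, while Egr1 and Entpd3 lost it without each of the 6 arrays (adjusted p up to 0.240 and 0.259, both without sham 3). Gas7 lost it without MCAO 2, MCAO 3, sham 2 or sham 3, with adjusted p of 0.104, 0.124, 0.0911 and 0.170.

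**Figure D2:**
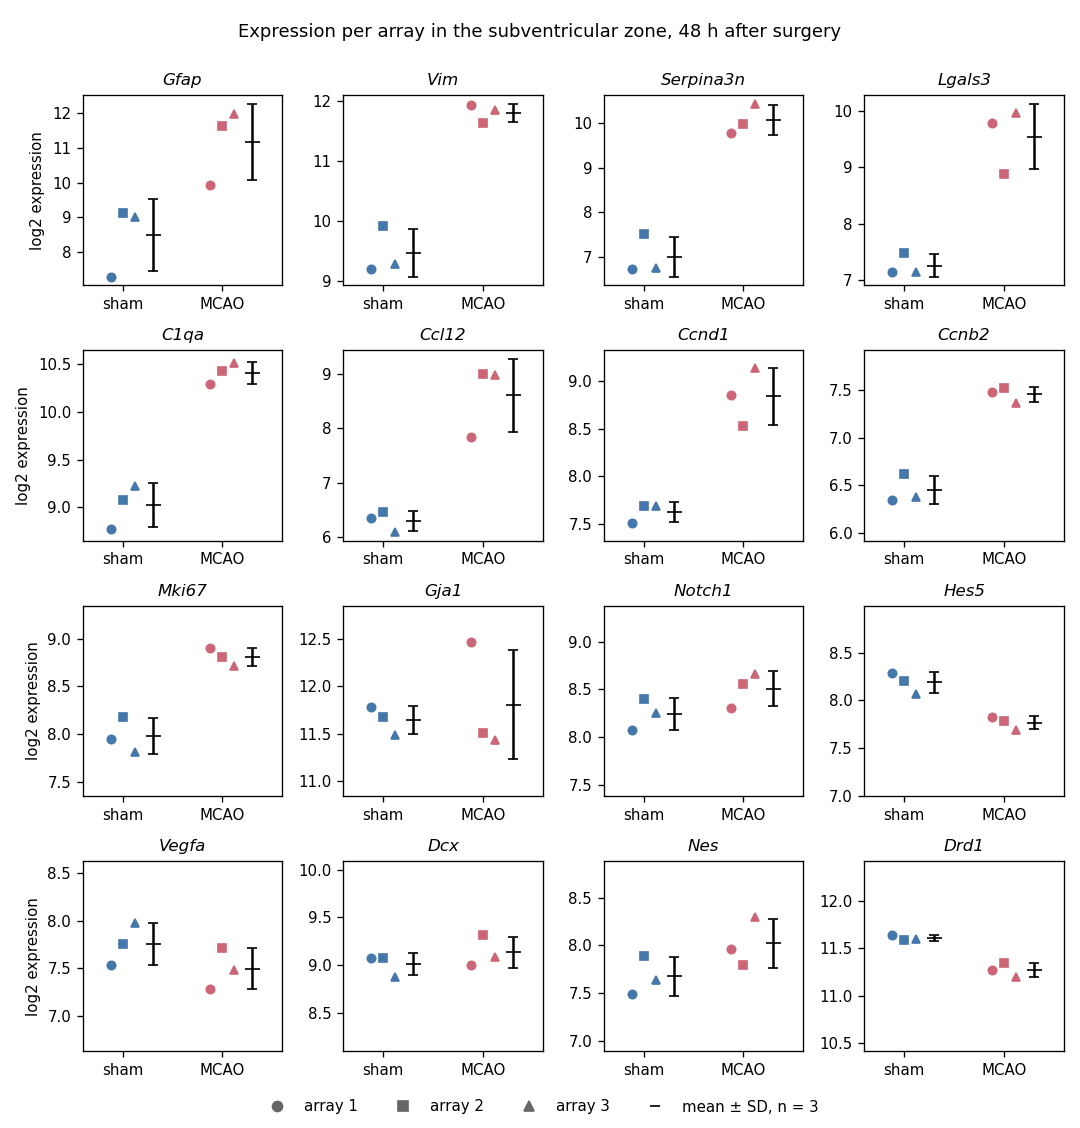
Quantile-normalised log2 expression of 16 genes on each of the 6 arrays, in sham (blue) and MCAO (red); the symbol gives the sample number, and the dash with its bar the mean ± SD of the 3 arrays of a group. All 3 MCAO values of Vim, Serpina3n, Lgals3, C1qa, Ccl12, Ccnd1, Ccnb2 and Mki67 lie above all 3 sham values, Gfap is lower on the arrays numbered 1 in both groups, and Gja1 is higher on MCAO 1 alone.

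Reactive astrocyte genes were among the strongest rises. Of 13 measured genes that mark reactive astrocytes across kinds of injury, 7 rose and 6 did not pass (11 rose when adjusted over the list alone), and all 13 were higher in MCAO, with a median of 1.51 log2. Cd44, S1pr3 and Serpina3n had the smallest p, each at an adjusted p of 0.00304. Of 9 genes tied to inflammation-type astrocytes 4 rose (6 adjusted over the list alone; median 0.86), among them the interferon-induced GTPase gene Gbp2 at 1.23, the proteoglycan gene Srgn at 0.98 and the immunoproteasome subunit Psmb8 at 0.94. Of 12 genes tied to ischemia-type astrocytes 4 also rose (8 adjusted over the list alone, 7 over all genes with the block; median 0.48), among them the endotoxin coreceptor Cd14 at 0.95, S100a10 at 1.43 and the pentraxin Ptx3 at 1.07. Without sham 3, Srgn (adjusted p = 0.0543), Psmb8 (0.0607) and Ptx3 (0.0841) lost their calls, as did Ptx3 without MCAO 2 (0.0523). Several of these genes are also expressed by other cells: Cd14 and Srgn are myeloid genes, and 5, 3 and 2 members of the 3 lists stand in other lists too. The camera test gave adjusted p = 1.13e-23, 4.10e-10 and 9.09e-13 for the 3 lists, and adjusted p = 0.0854 for each with an estimated correlation.

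Gfap, the intermediate filament gene most used as an astrocyte marker, averaged 11.17 ± 1.10 (SD, n = 3) in MCAO and 8.48 ± 1.03 in sham, a difference of 2.69 ± 0.63 log2 (SE). It did not pass without the block (adjusted p = 0.140) and did with it (adjusted p = 5.62e-07), with both arrays numbered 1 lower than the others of their group and differences of 2.62, 2.49 and 2.95 within the pairs. It also passed without MCAO 1 (adjusted p = 0.0239). Of 19 astrocyte markers of healthy tissue, 2 rose and 17 did not pass (4 rose and 1 fell adjusted over the list alone, 7 and 1 over all genes with the block; median 0.15). The folate enzyme gene Aldh1l1 rose by 0.89 and the water channel gene Aqp4 by 0.97, while the glypican Gpc5 read −0.40 (adjusted p = 0.0895, and 0.0125 with the block). Aldh1l1 lost its call without sham 3 (adjusted p = 0.0543), and Aqp4 without MCAO 3, sham 1, sham 2 or sham 3 (0.120, 0.0827, 0.144 and 0.200). All 19 lay above the median gene in sham. For the list camera's adjusted p was 0.0108, and adjusted p = 0.157 with an estimated correlation. The list's call was also lost without MCAO 1 (adjusted p = 0.133) or sham 2 (0.0536).

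Genes of microglia and other phagocytes rose as well. Of 25 measured markers of activated phagocytes, 12 rose and 13 did not pass (21 rose adjusted over the list alone, 19 over all genes with the block), and 24 were higher in MCAO, with a median of 0.87 log2. The high-affinity Fc receptor gene Fcgr1 rose by 1.35 ± 0.11 (SE, n = 3 per group), the lysosomal protease gene Ctsz by 1.15 and Cd14 by 0.95. Of 15 markers of homeostatic microglia 2 rose (6 adjusted over the list alone, 8 over all genes with the block; median 0.37): the Fc receptor-like gene Fcrls, by 1.58, and the secreted-protein gene Olfml3, by 1.23. The ADP receptor gene P2ry13 read 0.43 higher (adjusted p = 0.135, and 0.0114 with the block). Of 18 markers of infiltrating monocytes or macrophages 6 rose (9 adjusted over the list alone; median 0.29), with Vim, which glia also express, the mannose receptor gene Mrc1 at 0.96 and Ms4a6c at 0.70 first by p. In sham tissue, 14 of the 25 activated phagocyte markers, 13 of the 15 homeostatic markers and 2 of the 18 monocyte markers lay above the median gene. Olfml3 lost its call without MCAO 2 (adjusted p = 0.0683), MCAO 3 (0.0896) or sham 3 (0.0892), and Ms4a6c without sham 3 (0.0557). Tested by camera the lists had adjusted p = 5.64e-31, 1.44e-09 and 2.28e-10 in that order, and adjusted p = 0.0854 for each with an estimated correlation.

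Among markers of neutrophils and lymphocytes, Lcn2 alone passed. Of 17 neutrophil markers 1 rose, both over all genes and adjusted over the list alone (median 0.11), namely Lcn2, an iron-sequestering lipocalin also listed for reactive astrocytes, by 1.80 ± 0.16 log2 (SE, n = 3 per group). The C-type lectin gene Clec4d and the calprotectin gene S100a8 read 0.29 and 0.24 higher without passing (adjusted p = 0.369 and 0.377). In sham 1 of the 17 lay above the median gene, and 4 stand in other lists. The neutrophil list had a camera adjusted p of 0.00144, and adjusted p = 0.360 with an estimated correlation. Of 16 lymphocyte markers 0 passed, over all genes or adjusted over the list alone, and 1 of them lay above the median gene in sham. The B-cell receptor component Cd79b read 0.22, and the T-cell genes Cd3g and Cd8b1 read 0.14 and −0.11. Their median was −0.0027, their mean 0.0031 and camera's direction upward (adjusted p = 0.912).

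Some genes of innate immune pathways rose in the same samples, though by camera their lists passed only at the preset correlation. Of 23 type I interferon response genes, 7 rose and 16 did not pass (19 rose adjusted over the list alone, 16 over all genes with the block), and all 23 were higher in MCAO (median 0.61): the antiviral membrane protein gene Ifitm3 rose 3.13-fold, the signalling factor Irf9 1.54-fold and the oligoadenylate synthetase-like gene Oasl2 2.20-fold. Of 14 complement genes 5 rose (7 adjusted over the list alone; median 0.34), led by C1qa, C1qb and C1qc, the subunits of the initiator of the classical pathway, at 2.63-fold, 2.58-fold and 2.85-fold. Of 14 antigen presentation genes 2 rose (12 adjusted over the list alone, 9 over all genes with the block; median 0.38), Psmb8 and the class I gene H2-K1, by 0.89 log2; the class I gene H2-D1 read 0.86 higher (adjusted p = 0.0634, and 0.00155 with the block). Both class I genes were read by probe sets that may bind related transcripts. Of 31 cytokine and chemokine genes 3 rose (6 adjusted over the list alone, 8 over all genes with the block; median 0.14), the chemokines Ccl3 by 0.67, Ccl12 by 2.30 and Ccl6 by 0.61. Without sham 3, Ifitm3, Irf9, Oasl2, Psmb8, H2-K1, Ccl3, Ccl12 and Ccl6 lost their calls, at adjusted p = 0.0841, 0.0900, 0.0923, 0.0607, 0.129, 0.0900, 0.0900 and 0.158. Without MCAO 3, Ifitm3, Irf9, H2-K1, Ccl3, Ccl12 and Ccl6 did (0.0731, 0.0640, 0.134, 0.0685, 0.0685 and 0.127), and without sham 2, Irf9, Oasl2, H2-K1, Ccl3 and Ccl6 did (0.0520, 0.0560, 0.113, 0.0566 and 0.103). H2-K1 and Ccl6 also lost theirs without sham 1 (0.0786 and 0.0900), Ifitm3 did without MCAO 2 (0.0521), and H2-D1 passed without MCAO 2 (0.0131). These lists had camera adjusted p-values of 1.38e-23, 1.26e-10, 1.15e-13 and 3.65e-07 in that order. With an estimated correlation camera gave adjusted p = 0.0854 for interferon, complement and antigen presentation and 0.157 for cytokines. The cytokine list did not pass when dimmer genes were left out (0.0557).

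Cell cycle genes rose as a group. All 45 measured members were higher in MCAO, with a median of 0.52 log2; 14 rose and 31 did not pass (39 rose adjusted over the list alone, and 36 over all genes with the block). The mitotic cyclin Ccnb2 rose by 1.01 ± 0.096 (SE, n = 3 per group), the thymidine salvage kinase Tk1 by 0.73, the G1 cyclin Ccnd1 by 1.21 and the proliferation marker Mki67 by 0.83 (adjusted p = 0.0134). Mki67 lost its call without MCAO 2 (adjusted p = 0.0532), MCAO 3 (0.0517) or sham 3 (0.0768). Tk1 and Ccnd1 lost theirs without sham 3 (0.0807 and 0.0743). In sham, 16 of the 45 lay above the median gene. By camera the adjusted p of the list was 1.48e-40, and adjusted p = 0.0854 with an estimated correlation.

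Some markers of neural stem cells rose. Of 23 neural stem cell markers, 3 rose and 20 did not pass (4 rose and 1 fell adjusted over the list alone, 5 and 2 over all genes with the block; median 0.11): the tetraspanin Cd9 rose by 1.06, the fatty acid carrier Fabp7 by 1.66 and the adhesion molecule Vcam1 by 0.82, all 3 also expressed by other glia or vessels. Nes, the intermediate filament of neural progenitors, averaged 8.02 ± 0.26 in MCAO and 7.68 ± 0.20 in sham (SD, n = 3; adjusted p = 0.575). Of its 3 probe sets 2 differ in sign from the brightest. Without sham 3, Cd9, Fabp7 and Vcam1 lost their calls (0.0574, 0.158 and 0.240). Fabp7 and Vcam1 also did without MCAO 3 (0.0700 and 0.174) or sham 1 (0.0926 and 0.0979), Fabp7 without MCAO 2 (0.114) and Vcam1 without sham 2 (0.145). The stem cell list had a camera adjusted p of 0.0612, and 0.0356 with the block; with an estimated correlation it gave adjusted p = 0.360 without the block and 0.298 with it. Without the block the list passed when MCAO 3 or sham 1 was left out (adjusted p = 0.0138 and 0.0421).

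Of 14 markers of transit-amplifying progenitors 0 passed, over all genes or adjusted over the list alone, with a median of 0.11. The smallest p-values belonged to the replication helicase gene Mcm2 (0.41), the ribonucleotide reductase gene Rrm2 (0.77) and the growth factor receptor gene Fgfr3 (0.27); Mcm2 and Rrm2, which are cell cycle genes, passed with the block at adjusted p = 0.00696 and 0.0131. Of the 14, 9 stand in other lists. The progenitor list had a camera adjusted p of 0.0406, and adjusted p = 0.276 with an estimated correlation; without MCAO 2, sham 1 or sham 2 it gave 0.471, 0.114 and 0.0572.

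None of 19 neuroblast markers passed (1 higher and 2 lower adjusted over the list alone, and 2 rose and 1 fell over all genes with the block). Dcx, the microtubule protein of migrating neuroblasts, averaged 9.13 ± 0.16 in MCAO and 9.01 ± 0.12 in sham (SD, n = 3; adjusted p = 0.896). The cytoskeletal gene Dpysl3 read 0.38, the interneuron transcription factor Dlx6 −0.33 and the doublecortin-like kinase Dclk1 −0.30, with adjusted p = 0.174, 0.226 and 0.229. With the block Dpysl3 rose and Dclk1 fell (adjusted p = 0.0141 and 0.0320), although 3 of the 9 probe sets of Dclk1 read higher, 1 of them at an unadjusted p under 0.05. The list's median was −0.013, its mean 0.035 and camera's direction downward without the block (adjusted p = 0.912).

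Notch signalling, which keeps neural stem cells undifferentiated, showed no shift as a group. Of 34 Notch pathway genes 0 passed (1 lower adjusted over the list alone, Hes5; 2 rose and 1 fell over all genes with the block; median 0.056, 22 higher). Notch1, the receptor, read 8.51 ± 0.18 in MCAO and 8.24 ± 0.17 in sham (SD, n = 3; adjusted p = 0.628), its ligand Jag1 differed by −0.053 ± 0.13 log2 (SE; adjusted p = 0.980) and the target Hes1 by 0.21 ± 0.090 (adjusted p = 0.554). Hes5, the other target, read −0.42 ± 0.085 and over all genes passed with the block but not without it (adjusted p = 0.00407 and 0.0815), with differences of −0.47, −0.43 and −0.38 within the pairs. With the block the ubiquitin ligase gene Dtx4 and the protease gene Adam17, at 0.50 and 0.30, rose too (adjusted p = 0.146 and 0.212 without it, 0.0202 and 0.0345 with it). Camera's adjusted p was 0.221. Notch1 read in the opposite direction on 1 of its 2 probe sets, and Hes5 was read by a probe set that may bind related transcripts. Jag1 changed sign without MCAO 3 or without sham 1, at 6.3e-05 and 0.032.

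None of 39 measured genes of the astrocytic calcium wave machinery passed (1 higher adjusted over the list alone, and 3 rose and 2 fell over all genes with the block; median −0.023, 17 higher; camera adjusted p = 0.548). Gja1, which encodes the gap junction protein connexin 43, read 11.80 ± 0.57 in MCAO and 11.65 ± 0.15 in sham (SD, n = 3; adjusted p = 0.965), on a probe set that may bind related transcripts, and its difference turned from 0.16 to −0.17 without MCAO 1. The UDP receptor gene P2ry6, which microglia express, read 0.77 higher, the store-operated calcium channel gene Orai1 0.31 and the phospholipase gene Plcd4 0.39, with adjusted p = 0.0660, 0.182 and 0.287. All 3 passed with the block, at adjusted p = 0.00323, 0.0283 and 0.0149. S100 and annexin genes formed a separate list, in which 7 of 16 rose (13 adjusted over the list alone, 11 over all genes with the block). All 16 were higher, and the median was 0.58. S100a6, S100a10 and S100a4, of the S100 family of small proteins, rose by 1.79, 1.43 and 1.80 log2. S100a4 lost its call without MCAO 3 (adjusted p = 0.0504) or sham 3 (0.0734). This list had a camera adjusted p of 5.22e-22, and adjusted p = 0.0854 with an estimated correlation.

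None of 33 hypoxia response genes passed (1 higher adjusted over the list alone; median 0.024, camera adjusted p = 0.548). Vegfa, the angiogenic growth factor induced by hypoxia, read 7.50 ± 0.21 in MCAO and 7.76 ± 0.22 in sham (SD, n = 3; adjusted p = 0.738). The glycolytic gene Hk2 read 0.77, the mitophagy gene Bnip3 −0.26 and the growth regulator Ddit4 −0.40, at adjusted p = 0.0784, 0.248 and 0.330. With the block Hk2 rose (adjusted p = 5.70e-04) and Bnip3 and Ddit4 fell (adjusted p = 0.0484 and 0.0395). Secreted growth factors and receptors acting on neural progenitors did not pass either, with 0 of 34 past the threshold over all genes or adjusted over the list alone, 3 risen with the block, a median of −0.049 and a camera adjusted p of 0.488. The EGF-family ligand Hbegf read 0.54 (adjusted p = 0.166, and 0.00361 with the block), Fgf9 −0.26 (adjusted p = 0.332) and Igf1 0.37 (adjusted p = 0.388, and 0.0268 with the block).

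Neuronal genes were lower in MCAO by small amounts. Of 27 synaptic transmission genes 26 were lower, with a median of −0.20 log2, and none passed, over all genes or adjusted over the list alone, while 2 fell with the block. The vesicle fusion genes Snap25 and Syt1 read −0.24 and −0.21 (adjusted p = 0.377 and 0.418), and the synaptic kinase gene Camk2a −0.74 (adjusted p = 0.481, and 0.0291 with the block). Within the pairs Camk2a differed by −0.070, −1.25 and −0.90. Its 6 probe sets read from −0.74 to −0.022, 1 of them at an unadjusted p under 0.05. Of 22 striatal neuron markers 21 were lower, also with a median of −0.20, and none passed (1 lower adjusted over the list alone, 5 over all genes with the block). The dopamine receptor gene Drd1 read −0.34, Ido1 −0.39 and the adenylyl cyclase gene Adcy5 −0.27. With the block these 3 fell, at adjusted p = 0.0179, 0.00871 and 0.0404 against 0.101, 0.349 and 0.356 without it. These are quantile-normalised values, on which the block gave 236 falls over all genes, against 51 on the values as deposited. Camk2a passed without MCAO 1 (0.0383). All 22 striatal markers lay above the median gene in sham. The synaptic and striatal lists had camera adjusted p = 9.58e-06 and 6.92e-08, and adjusted p = 0.111 and 0.0854 with an estimated correlation.

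Of 18 markers of cortical, hippocampal or septal neurons 15 were lower (median −0.080), and none passed over all genes or adjusted over the list alone, while 1 fell with the block. The channel gene Trpc4 and the transcription factors Cux2 and Lhx6 read −0.19, −0.15 and −0.17. Camera's adjusted p for them was 0.0233, and adjusted p = 0.131 with an estimated correlation, and the call was lost without MCAO 2, sham 1 or sham 3 (adjusted p = 0.0838, 0.106 and 0.0882). Immediate early genes are induced within minutes by neuronal activity and other stimuli. Camera called their list lower at the preset correlation (adjusted p = 0.00928), but not with an estimated correlation (adjusted p = 0.360). By fry the list did not pass (adjusted p = 0.300), and 7 of its 26 members were higher. Of 26, 1 fell, Egr1, and 25 did not pass (2 fell adjusted over the list alone, and 4 fell and 1 rose over all genes with the block; median −0.096), while Atf3, an injury-induced member, read 0.32 higher (adjusted p = 0.255). Egr1 lost its call without each array in turn. The list also lost its camera call without sham 3 (adjusted p = 0.10).

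Some matrix genes rose, while the vessel lists did not pass. Of 32 extracellular matrix genes 2 rose and 30 did not pass (6 rose adjusted over the list alone, and 8 rose and 1 fell over all genes with the block; median 0.097): the metalloproteinase inhibitor Timp1 rose by 1.38 ± 0.17 log2 (SE, n = 3 per group) and fibronectin, Fn1, by 0.61. The macrophage elastase gene Mmp12 read 0.99 (adjusted p = 0.182, and 0.00717 with the block). Of 19 markers of pericytes, smooth muscle or fibroblasts, Tagln alone passed, rising by 1.95, both over all genes and adjusted over the list alone; Col1a2 and Dcn read 0.32 and 0.19, and the median was 0.048. Of 18 endothelial markers 0 passed, over all genes or adjusted over the list alone (median 0.044): the lactate transporter Slc16a1 read 0.59 (adjusted p = 0.283, and 0.00235 with the block), the tight junction gene Cldn5 0.28 and the transporter Slco1c1 0.37. Timp1 and Tagln lost their calls without sham 3 (adjusted p = 0.0841 and 0.0892). Fn1 lost its call without every array but MCAO 2, with adjusted p from 0.0768 without MCAO 1 to 0.180 without sham 3, and Mmp12 passed without MCAO 2 (0.0481). Of the mural markers 8 stand in other lists. The matrix list had a camera adjusted p of 1.36e-05, and adjusted p = 0.157 with an estimated correlation. The mural list had 0.136 and the endothelial list 0.146, which passed at 0.00792 without MCAO 2.

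Genes of the cells lining the ventricle did not pass over all genes tested. Of 23 ependymal markers 21 were higher (median 0.15; 0 adjusted over the list alone, 1 risen with the block), with the ciliogenesis factor Foxj1 at 0.25, the dynein gene Dnah11 at 0.13 and the cilium gene Rsph1 at 0.25. This list had a camera adjusted p of 0.0303, and adjusted p = 0.666 with an estimated correlation. Without sham 3 or sham 1 it was 0.641 and 0.139, and without MCAO 2, where the direction turned, 0.852. Of 19 choroid plexus markers 1 was higher adjusted over the list alone (median 0.039; camera adjusted p = 0.303): the binding protein Igfbp2 read 1.11 (adjusted p = 0.0793, and 0.00219 with the block), the thyroid hormone carrier Ttr −0.28 and the bicarbonate transporter Slc4a5 0.13. Igfbp2 passed without MCAO 2 (0.0117).

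Of 19 mature oligodendrocyte markers 0 passed over all genes, 1 was higher adjusted over the list alone, and 2 rose and 2 fell with the block. The kallikrein Klk6 read 1.44 (adjusted p = 0.118) and the lipocalin Apod 0.79 (adjusted p = 0.298), both rising with the block (adjusted p = 8.75e-04 and 0.00164), and the aspartoacylase gene Aspa read −0.26. Both Klk6 and Apod passed without MCAO 2 (0.0103 and 0.0288). That list's median was −0.091, its mean 0.028 and camera's direction downward (adjusted p = 0.628), and it passed downward without sham 2 (adjusted p = 0.0206) or MCAO 3 (0.0411). Its direction turned upward, without passing, when MCAO 2 (mean 0.20, adjusted p = 0.0838) or sham 3 (0.21, 0.0704) was left out. Of 15 oligodendrocyte precursor markers 0 passed, over all genes or adjusted over the list alone. Tmem100 read 0.33 (adjusted p = 0.636, and 0.0295 with the block), Cacng4 −0.15 and Lhfpl3 0.12, which turned to −0.0053 without MCAO 1. The list's median was −0.0075, its mean 0.027 and camera's direction upward (adjusted p = 0.854).

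Of 19 cholesterol synthesis genes 16 were higher, with a median of 0.11 log2 and none past the threshold, over all genes or adjusted over the list alone. Sqle, the squalene epoxidase gene, read 0.32 (adjusted p = 0.268, and 0.0187 with the block), and Cyp51 and Tm7sf2, further enzymes of the pathway, read 0.25 and 0.21. Camera's adjusted p was 0.00556, and adjusted p = 0.0854 with an estimated correlation. Of 24 heat shock and unfolded protein genes none passed, over all genes or adjusted over the list alone, with a median of −0.015, a mean of 0.031 and camera's direction upward (adjusted p = 0.628). The chaperones Hspb8, Sdf2l1 and Hspa1a read 0.35, 0.29 and 0.19, and Hspb8 passed with the block (adjusted p = 0.319 without and 0.0404 with it). None of 6 measured red blood cell genes passed, over all genes or adjusted over the list alone (median 0.054; camera adjusted p = 0.792), with the haem synthesis gene Alas2 at −0.086, the globin gene Hbb-b2 at 0.078 and the membrane gene Epb42 at 0.056. Hbb-b2 and Epb42 changed sign with the mean of all probe sets, at −0.010 and −0.00065.

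**Figure D3:**
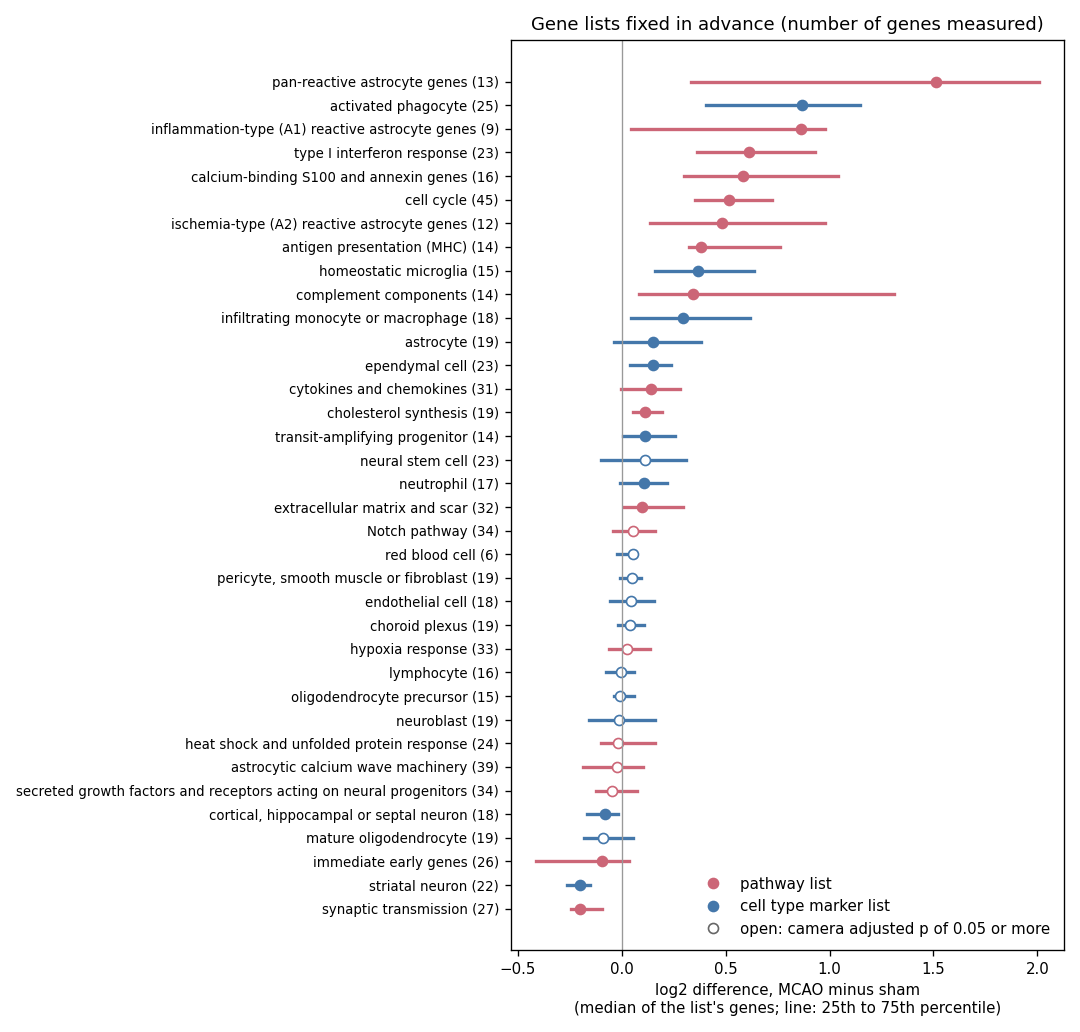
Median log2 difference, MCAO minus sham, of the measured genes of each of 36 lists (point) with its lower to upper quartile (line); red marks pathway lists, blue cell type marker lists, and filled points lists past the threshold by camera at the preset correlation. Pan-reactive astrocyte genes lie highest at 1.51 and activated phagocyte markers next at 0.87, while synaptic and striatal neuron genes lie lowest at −0.20.

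By camera at the preset correlation 22 of the 36 lists passed, 18 upward and 4 downward. With the block 23 passed, and none passed with an estimated correlation, for which the lowest adjusted p was 0.0854 without the block and 0.254 with it. Correlated genes alone do not account for this loss. The cholesterol list, with an estimated correlation of −0.045, below the preset 0.01, went from an adjusted p of 0.00556 to 0.0854 by camera. The list of cortical, hippocampal or septal neurons, at −0.014, went from 0.0233 to 0.131. By fry 14 lists passed, all upward.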

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

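Probe sets without a single gene symbol were set aside for the gene counts, and 25 of these 10092 rose in MCAO while 0 fell, when each probe set was tested on its own with limma and Benjamini-Hochberg adjustment. They are not analysed here by name. Groups of 3 arrays are too small for a test of a single deviating value.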

How the results depend on the processing

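The number of genes past the threshold was 206, and 1113 (877 rose, 236 fell) with the replicate block and 816 (765 rose, 51 fell) with the block on the values as deposited. The fits with the block differed only in the added quantile normalization, so the larger number of falls in the first came with that step. Which of them lies closer to the tissue was not tested. At an adjusted p of 0.01 it was 59, all risen, and at 0.1 it was 325 (313 rose, 12 fell). Leaving out each array in turn gave 44 (without sham 3) to 209 (without MCAO 1), and 31 (without sham 3) to 82 (without MCAO 2) genes changed at least 2-fold. All 206 genes kept their direction in each of these fits. Of the 22 lists, 0 passed by camera with an estimated correlation, 0 with that and the block, and 14 by fry.

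Some differences of genes and some directions of camera turned, and the cause was not tested. Camera compares the t-statistics of a list with those of all other genes, so its direction can turn while the list's mean keeps its sign. Hbb-b2 and Epb42 read −0.010 and −0.00065 with the mean of all probe sets. Gja1 read −0.11 without both arrays numbered 1, and −0.17 to 0.34 with each array left out in turn, Jag1 −0.17 to 0.032 and Lhfpl3 −0.0053 to 0.20. The hypoxia list's mean was 0.036, and −0.011 with the dimmer genes left out.

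Camera's direction for the neuroblast, lymphocyte, red blood cell and oligodendrocyte precursor lists, whose means were 0.035, 0.0031, 0.020 and 0.027, turned in the settings given next. The neuroblast list's mean, which stayed above 0 in them, was 0.067 as deposited, 0.056 with shifted medians, 0.032 with dimmer genes left out, 0.051 with the mean of all probe sets, 0.062 with array weights, 0.035 with the block and with the block and an estimated correlation, and 0.067 with the block on deposited values. The lymphocyte list's was 0.0033 as deposited with or without the block, −0.0073 with shifted medians, −0.023 with weights and −0.033 without the arrays numbered 1. The red blood cell list's was 0.017 as deposited with or without the block, 0.0069 with shifted medians and −0.013 with the mean of all probe sets. The oligodendrocyte precursor list's was −0.044 with weights and −0.026 without the arrays numbered 1. With each array left out in turn the means ran from 0.0034 to 0.073 for neuroblasts, −0.047 to 0.035 for lymphocytes, −0.0014 to 0.30 for ependymal cells, −0.12 to 0.21 for mature oligodendrocytes, −0.0055 to 0.090 for oligodendrocyte precursors and −0.011 to 0.056 for red blood cells.

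Not run were a pseudocount, since the values were already log2, the robust variance for lists, and each probe set on its own for lists and named genes.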

Other observations

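All tests of this section were chosen only after the result was seen, except the regroupings of the arrays and the comparison of second probe sets on the arrays numbered 1.

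The galectin genes Lgals1, Lgals3 and Lgals9 rose by 2.98, 2.29 and 1.08 log2, and Lgals3bp, which encodes a protein that binds galectin 3, by 0.97. These are 4 of 9 measured genes whose symbols start with Lgals (Fisher's exact test, 1-sided, adjusted p = 2.8e-04 over 309 symbol families). S100a genes did too, with 5 of 12 (adjusted p = 3.8e-05), S100a4, S100a6, S100a10, S100a13 and S100a16, as did 7 of 89 genes named Cd, for cell surface antigens (adjusted p = 0.00636; 18 with the block; median of the 89 genes 0.049), Cd9, Cd14, Cd44, Cd48, Cd52, Cd53 and Cd68.

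Outside the lists, and chosen after their values were seen, the protease inhibitor A2m rose by 1.83 ± 0.16 log2 (SE, n = 3 per group; adjusted p = 0.00405), Ly86, a partner of a Toll-like receptor homologue, by 1.85 (0.00194), the inflammasome adaptor Pycard by 1.52 (0.00304) and the small heat shock gene Hspb6 by 1.58 (0.0119).

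Of the 10 ways to split the 6 arrays into 3 and 3, the real one gave the most: 206 genes past the threshold against 0 for the highest other, 70 changed at least 2-fold against 0, and 22 lists against 19, so in each count 1 split reached the real value. With 10 splits a share under 0.05 cannot be reached. Among the 4 splits that part all pairs, the block gave 1113 genes for the real split and 0 for the highest other, and the highest other count of lists was 18. Every other split mixes MCAO with sham arrays, which puts differences between the groups into the spread. A gene count of 0 there is thus no measure of what chance would give.

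The arrays numbered 1 stand apart in both groups. A difference in labelling may account for this: the poly-A controls of the arrays numbered 1 lay 0.689 log2 away from the other 4, whose range was 0.579. The 18 hybridisation control probe sets did not set these arrays apart. They averaged 10.30 on MCAO 1 and 10.50 on sham 1, against 10.34 to 10.64 on the other 4. This argues against a hybridisation difference shared by both arrays, as far as these controls report it. Another cell makeup of the tissue taken could also set the arrays numbered 1 apart. For it, second probe sets should move like the brightest ones, and the median ratio was 0.463 (95% interval 0.40 to 0.545) against 0.750 (0.670 to 0.807) for MCAO minus sham. Since the ratio lay above 0.5 of that for MCAO, the bound written beforehand, a labelling difference and another cell makeup both remain open.

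Genes of activated phagocytes were higher in MCAO, with a median of 0.868 log2 (95% interval over genes 0.595 to 1.07), though 13 of 25 did not pass singly. Fry called the list upward (adjusted p = 0.00922), while camera did not with an estimated correlation, which was 0.475 for this list (adjusted p = 0.0854). Lists with an estimated correlation below the preset one lost their camera calls too, so this loss is not a measure of the correlation alone. Intervals over genes resample such correlated genes and measure no spread between arrays. A lower share of other cells would raise markers of other types alike, but the highest upper bound among the medians of 4 such lists was 0.210 (0.139 without sham 1, 0.420 without sham 2 and 0.311 without MCAO 1, against lower phagocyte bounds of 0.550, 0.604 and 0.436). Blood left in the tissue would raise haemoglobin probe sets, whose highest upper bound was 0.346, and without MCAO 1, where the bounds lay closest, 0.363 against 0.436. More microglia in an unchanged state could be part of it: homeostatic markers had a median 0.502 lower (permutation of genes, p = 0.0197), but p was 0.0516 without sham 1. A change of state of resident microglia and entry of cells from blood may contribute too, and neither was tested.

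Cell cycle genes were higher in MCAO, with a median of 0.516 log2 (95% interval over genes 0.410 to 0.606), though 31 of 45 did not pass singly. Fry called the list upward (adjusted p = 0.00922), while camera did not with an estimated correlation (adjusted p = 0.0854, and 0.254 with the block). The same bound of 0.210 argues against a lower share of other cells, for these genes and arrays only. It was 0.139 without sham 1, and 0.420 without sham 2, where the margin was small, against lower cell cycle bounds of 0.423 and 0.454. These bounds resample the genes of a list, which are correlated, and measure no spread between arrays. More transit-amplifying progenitors and neuroblasts should, by the prediction written for this explanation, raise their markers outside the cell cycle list as much. The median of these markers was 0.0447 (−0.0149 to 0.127), below the cell cycle interval, which argues against a rise of that size in them. But 27 of the 31 lie above the median gene in sham, a level that would hide a small share. That limit was not part of the prediction, and with it the explanation stays open. Dividing cells of another type, such as microglia or astrocytes, may account for the rise of cell cycle genes too, which was not tested.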
